A study of Homo sapiens with 10 samples.

How the data were processed

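RNA of 10 clones of the human prostate cancer line PC-3 was measured on a 1-channel Affymetrix array after biotin labelling, per the labels' protocols, with 5 clones carrying CENPU in a lentiviral vector and 5 carrying the empty vector. The values used were log2 expression values deposited by the authors, 1 column per clone and 53617 probe-set rows, ranging from 1.65 to 15.0. Partek and RMA were named without versions per the submitters' processing notes, and RMA comprises background correction, quantile normalization between arrays and summary of probes. The log2 scale was inferred from the range of the deposited values, because the sources used here do not state it. The quantiles of the columns were close but not identical, and what followed RMA is not given in the sources used here. Arrays have no total count, so depth does not apply, and the number of clones limited the precision. RMA assumes that most transcripts keep their level between arrays, so a change shared by most genes would have been removed from these values. Background signal remains in dim rows and makes their differences too small.

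Rows were named through a platform table that pairs probe sets with gene symbols, and symbols were updated by gene ID to the RefSeq gene table of the human assembly GRCh38.p14. It gave 1 symbol for 16098 rows, several for 0 and none for 37519, and all 16098 matched by gene ID. The named rows covered 14884 genes, of which 11916 were protein-coding. Many gene families thus had few named rows, and the 37519 unnamed rows were not used in gene counts. The 779 genes with several rows were represented by the row of highest mean, and in 1 gene several rows passed in opposite directions. The genome build of the array annotation is not given in the sources used here, so RefSeq was used only for names, gene type, genomic span and which genes neighbour each other.

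Groups were taken from the sample labels. The clones are described as separate isolates, so p-values measure the spread between clones. Each row was tested with limma (version 3.58.1, R 4.3.3), with lmFit on the deposited log2 values and eBayes with a constant prior, without covariates. Benjamini-Hochberg adjustment ran over the 16098 named rows, and a gene passed at an adjusted p under 0.05. Gene lists were tested with camera and the correlation between genes estimated from the residuals, with Benjamini-Hochberg adjustment over 36 lists. The 38 lists held 832 entries, of which 497 were measured. Lists with fewer than 5 measured members were not tested, a minimum set after the matches had been counted. Single values were compared with exact two-sided permutation tests. Separation of the groups was the share of the sum of squares between them, and spread was the mean distance of clones to their group centroid. The span trend was measured as Spearman's correlation with the genomic span of the gene.

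The design, gene lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took CENPU, then in each direction the 12 genes with the largest log2 difference among those that passed and whose groups did not overlap, and up to 4 members of each list by smallest p. Symbols that are locus identifiers, microRNAs, small RNAs or olfactory receptors were counted but not used to fill these places. Further list members, whether they passed or not, were chosen for naming after their values were seen.

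The fit was tested on simulated data in which 200 of 16098 rows were changed. It recovered 40% of the rows changed by a log2 difference of 0.5, 96% at 1, 98% at 2 and 100% at 3, and 4.57% of its calls were false. The simulated noise was drawn separately for each row, whereas rows of the real arrays shared clone-wide trends. These shares therefore do not carry over to the real calls. Alternatives were quantile normalization and median centring of the deposited values, a filter on dim rows, all rows of the table, array weights, eBayes with trend and robust fitting, ordinary variances, thresholds of 0.01 and 0.10, a block by clone number, camera with preset correlation or ranks, fry, the 2000 most variable genes, and leaving out each clone. Removal of the gene span trend by loess, and leaving out control 2, CENPU 7 and CENPU 13 together, were added after the data were examined. No scanner files were used here, so background was not assessed for single probes.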

Results

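PC-3 is an established human cell line derived from a prostate cancer metastasis to bone. Cells of this line had received a lentiviral vector that was either empty or carried CENPU, had been selected with blasticidin, and had been grown out as single-cell clones. RNA from 5 CENPU clones (numbers 1, 4, 5, 7 and 13) and 5 empty-vector control clones (numbers 1 to 5) was hybridised to Affymetrix arrays, with 1 array per clone. CENPU encodes a subunit of the constitutive centromere network, the group of proteins that stays on centromeric chromatin and anchors the kinetochore. The comparison asked which transcripts differed between PC-3 clones that overexpressed CENPU and clones that carried the empty vector. The deposited table held log2 expression values for 53617 probe sets, and array medians lay between 4.62 and 4.76. Pearson correlations between arrays across named rows were 0.954 to 0.991 within the CENPU group, 0.976 to 0.993 within the control group and 0.916 to 0.986 between the groups. No 2 arrays held identical values. The number of clones, 5 in each group, limited the precision of every comparison.

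CENPU was expressed 8.44-fold higher in the CENPU clones than in the controls. Its probe set averaged 9.34 ± 0.43 (SD, n = 5) in CENPU clones and 6.26 ± 0.29 (SD, n = 5) in control clones on the log2 scale. The log2 difference was 3.08 with a standard error of 0.20 (limma, Benjamini-Hochberg adjusted p = 2.89e-05). The CENPU clones ranged from 8.70 in clone 5 to 9.84 in clone 13, and the control clones from 5.78 in clone 2 to 6.56 in clone 5, so every clone matched its label. The exact two-sided permutation test gave p = 0.00794, the smallest value that assignments of these clones allow. Genes on either side of CENPU were examined as a list of 18 neighbours. Among its 13 measured members, UFSP2 and TRAPPC11 rose, by log2 differences of 0.92 and 1.21, 0 fell and 11 did not pass. The median log2 difference was 0.03, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.658 with an estimated correlation).

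**Figure D1:**
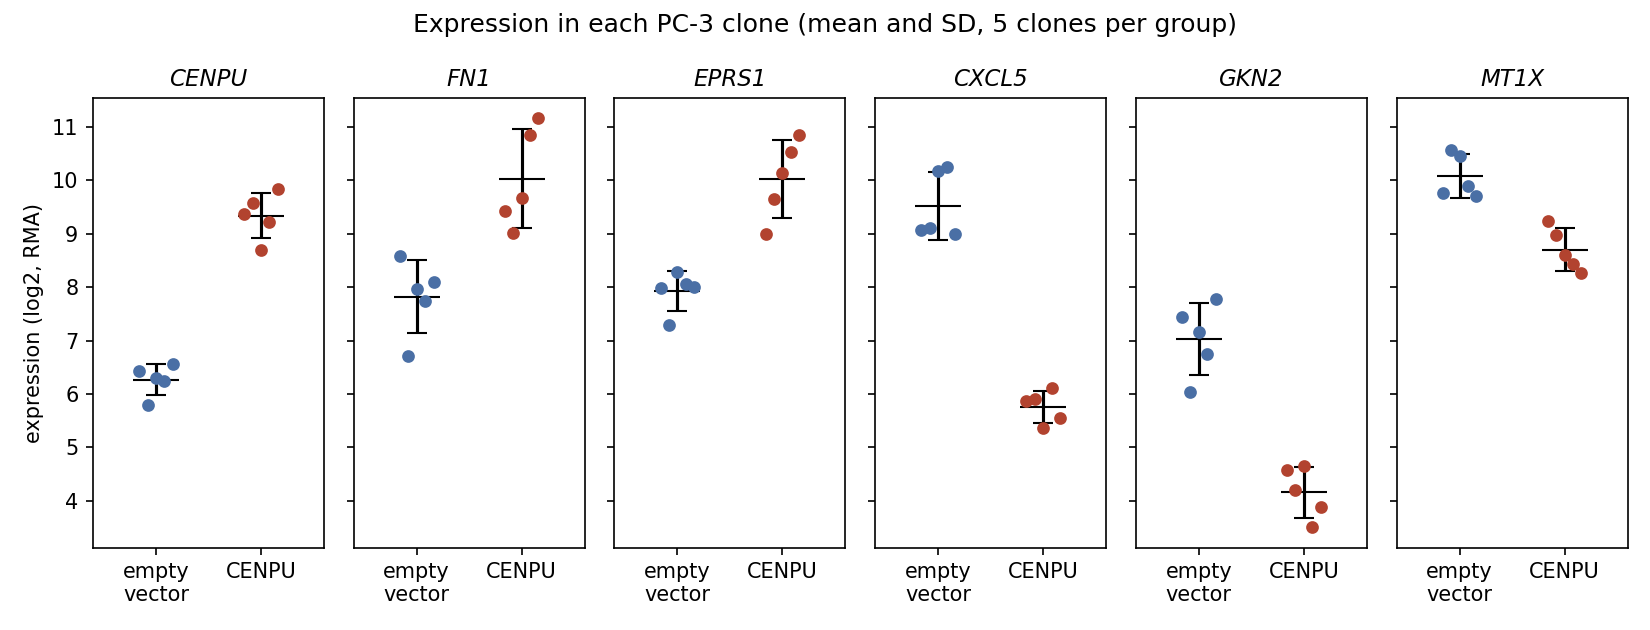
Expression of 6 genes on the log2 scale (vertical axis, RMA values) in 5 empty-vector clones (blue) and 5 CENPU clones (red). Each point is 1 clone, the horizontal bar is the group mean and the whiskers are 1 SD. For each of these genes the groups did not overlap, and CXCL5 averaged 9.52 in control clones against 5.76 in CENPU clones.

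The chemokine gene CXCL5, whose product attracts neutrophils, had the largest fall of any named gene, 13.5-fold. It averaged 5.76 ± 0.30 (SD, n = 5) in CENPU clones against 9.52 ± 0.63 (SD, n = 5) in control clones (limma adjusted p = 4.68e-05). GKN2, which encodes a secreted gastrokine, fell 7.33-fold, with a log2 difference of -2.87 and a standard error of 0.31 (limma adjusted p = 0.00154). Among the genes that rose, FN1, encoding the matrix glycoprotein fibronectin, was 4.61-fold higher (log2 difference 2.21, standard error 0.43, limma adjusted p = 0.0124). EPRS1, the glutamyl-prolyl-tRNA synthetase, was 4.30-fold higher (log2 difference 2.11, standard error 0.31, limma adjusted p = 0.00401).

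The next largest rises were in TSPAN6, a tetraspanin (1.91 on the log2 scale), ESD, which encodes S-formylglutathione hydrolase (1.84), and AQR, a spliceosomal RNA helicase (1.84). The RPL21P28 row, at 1.77, belongs to a ribosomal protein pseudogene, and its signal cannot be assigned to that copy with certainty. CCNG1, encoding cyclin G1, and WASHC5, a subunit of the WASH complex, each rose by 1.76. MTREX, the helicase that feeds RNA to the nuclear exosome, rose by 1.71, and MAP2K6, a kinase upstream of p38, by 1.68. IQGAP1, a cytoskeletal scaffold protein, and PREPL, a serine hydrolase, each rose by 1.67. The genes that fell beyond CXCL5 and GKN2 did so by smaller amounts. Among genes whose groups did not overlap, the metallothionein MT1X fell by 1.38, the siderophore-binding lipocalin LCN2 by 1.31 and RSRP1 by 1.28. TFPI2, a serine protease inhibitor, fell by 1.27, the cytokine IL32 by 1.22, and ZC3H12A, an endoribonuclease that degrades cytokine mRNAs, by 1.12. EFNA4, RALGDS, LRRC14 and EDN1, the last encoding endothelin-1, each fell by 1.03. These genes were picked by size among those that passed and whose groups did not overlap, and their limma adjusted p ran from 4.68e-05 to 0.0375. BST2 fell further than MT1X, by 2.20, but its groups overlapped. The microRNA rows MIR578 and MIR1471 had larger log2 differences than CENPU, at 4.81 and 3.33. Both lay outside the rule for named genes and are named here after their values were seen.

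Across 14884 genes, 1504 differed between the groups (limma, Benjamini-Hochberg over 16098 rows), 791 higher and 713 lower in CENPU clones. At a log2 difference of at least 1, 239 were higher and 25 lower. At an unadjusted p under 0.05 there were 4147 genes, where 744 would be expected by chance. The values of the groups did not overlap for 1448 genes, 9.73% of all genes against the 0.794% that chance gives with 5 clones in each group, and 1145 of these were among the 1504. Of the 1504, 1389 were protein-coding, 55 encoded microRNAs and 36 were long non-coding RNAs. The count was 613 without control clone 4 and 2471 without CENPU clone 1, and it was 470 without control 2, CENPU 7 and CENPU 13 together. The balance of directions depended on the scaling of the arrays, with 754 higher and 952 lower after quantile normalization and 731 higher and 911 lower after median centring.

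The direction of change went with the genomic span of the genes. Among 11916 protein-coding genes, 273 of the longest quintile were higher and 41 lower in CENPU clones, whereas in the shortest quintile 52 were higher and 200 lower. Spearman's correlation between span and log2 difference was 0.327 across these genes, which are not independent replicates. The same correlation was computed in each clone from its deviation from the mean of all clones. It was 0.360 in CENPU 13, 0.316 in CENPU 7, 0.197 in CENPU 5, -0.0358 in CENPU 4 and -0.160 in CENPU 1. In control clones it was -0.0934 in clone 1, -0.355 in clone 2, -0.163 in clone 3, -0.279 in clone 4 and -0.165 in clone 5. The group means were 0.135 ± 0.225 (SD, n = 5) and -0.211 ± 0.105 (SD, n = 5), with exact two-sided permutation p = 0.0159. With the trend removed from each array, 1462 genes passed, 1298 of them among the 1504. Removal changed the log2 differences of protein-coding genes by a median of 0.0807 in absolute size, so it could end few calls. The shared calls thus do not show that these differences are separate from the order of the clones along the trend. Without the 3 clones at its ends, FN1 differed by 1.28 and EPRS1 by 1.51, and MTREX (1.04), MAP2K6 (1.39), PREPL (1.14), TFPI2 (-1.31), ZC3H12A (-0.98) and EDN1 (-1.10) no longer passed (limma adjusted p from 0.0535 to 0.117). CXCL5 differed by -3.91 and GKN2 by -2.81 without those clones. Of the 87 named genes, 46 no longer passed in that fit of 7 clones, and they kept a median of 80.5% of their log2 difference, from 48.0% to 122%, so the loss of a call there does not show that a difference went away.

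**Figure D2:**
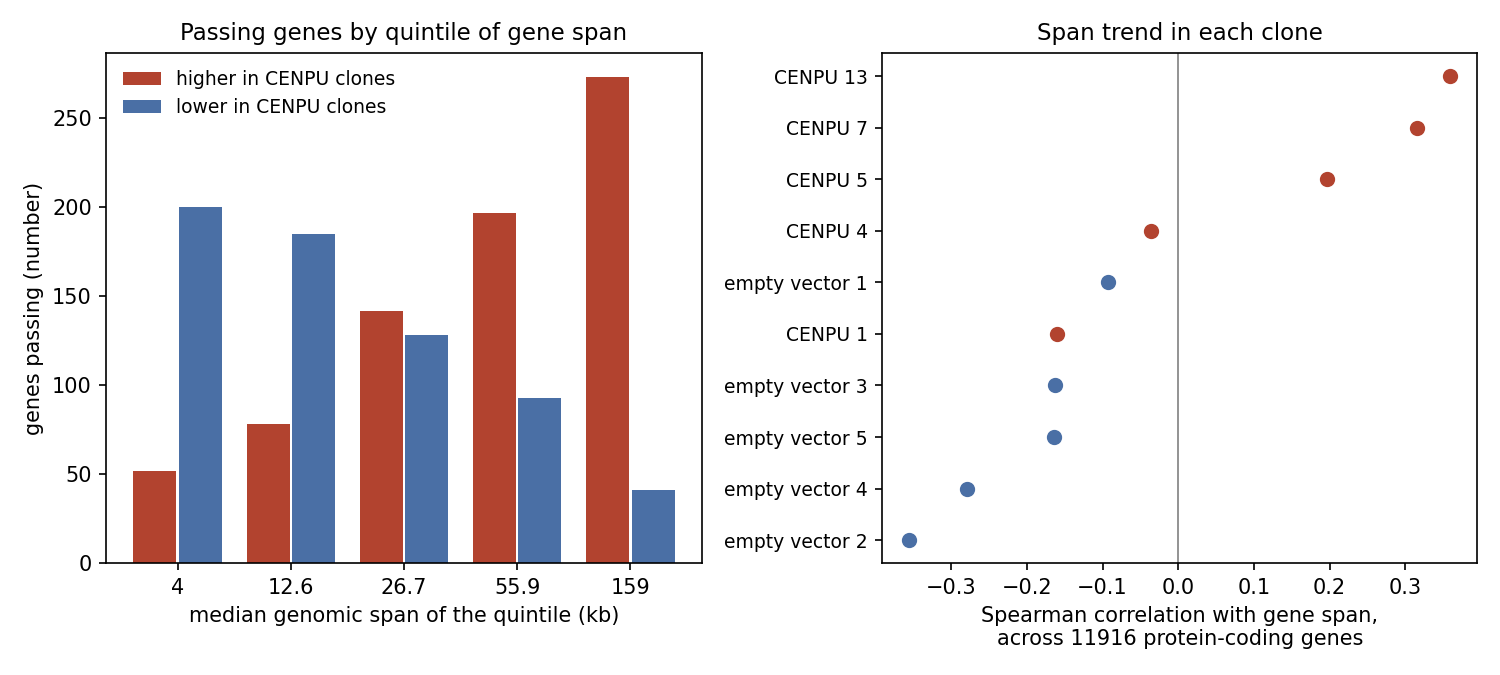
Left, the number of protein-coding genes higher (red) or lower (blue) in CENPU clones in each quintile of genomic span, labelled with the median span of the quintile in kilobases. Right, Spearman's correlation of each clone's deviation from the mean of all clones with gene span, with CENPU clones in red and empty-vector clones in blue. The longest quintile held 273 higher and 41 lower genes, and the clone values ran from -0.355 to 0.360.

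A second feature of the arrays also moved with the groups. Of the 199 unnamed rows that follow the last named row of the table, 35 passed, and all 35 were lower in CENPU clones, by a median log2 difference of -1.95, or 3.87-fold. The block was taken up only after its values were seen, and those 35 rows were picked because they passed, so their difference is not a test. All 47 rows of the block with means over 8, of which 30 passed and 17 did not, averaged 10.2 ± 0.288 (SD, n = 5) in CENPU clones and 11.5 ± 0.259 (SD, n = 5) in control clones. The 17 had a median log2 difference of 0.05.

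Of 18 measured members of the NF-kB and inflammatory cytokine list 8 fell, 0 rose and 10 did not pass, with a median log2 difference of -0.53, and 11 were lower and 0 higher adjusted over the list alone. Besides CXCL5, the neutrophil chemokine CXCL2 fell by 1.00 on the log2 scale, CXCL3 by 0.96, and the adhesion receptor ICAM1 by 0.75. NFKB2 and RELB, subunits of the non-canonical NF-kB dimer, fell by 0.52 and 0.54, and the colony-stimulating factors CSF3 and CSF1 by 0.83 and 0.61. CXCL8 and CCL20 had log2 differences of -1.14 and -1.22 and did not pass. The list passed with a preset correlation of 0.01 (camera adjusted p = 4.38e-05) and with fry (adjusted p = 0.00232), but not in the chosen test (camera adjusted p = 0.436 with an estimated correlation). Without control 2, CENPU 7 and CENPU 13, 5 members fell and the median was -0.49.

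Immediate early genes, whose transcripts respond within minutes to growth factors and stress, had a median log2 difference of -0.25. IER3, JUNB and DUSP1 fell, by 0.66, 0.99 and 0.51, 0 of the 16 measured members rose, and 13 did not pass. There were 3 lower adjusted over the list alone (camera adjusted p = 0.015 with the preset correlation and adjusted p = 0.514 with an estimated correlation). In the list of NRF2 targets and metallothioneins, MT1X and MT2A fell, by 1.38 and 0.58, and 7 of 9 measured members did not pass, with 2 lower adjusted over the list alone (adjusted p = 0.514 with an estimated correlation). Of 28 measured interferon-stimulated genes, BST2, USP18 and IFITM3 fell, by 2.20, 0.58 and 0.47, SAMD9L rose by 0.49, and 24 did not pass, with 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.906 with an estimated correlation). Leaving out CENPU 13 or control 4 gave 1 higher and 0 lower interferon-stimulated genes. Over all fits without 1 clone, 0 to 2 of them were higher and 0 to 5 lower. Among the 4 measured antigen presentation genes, too few for the list test, TAPBP fell by 0.43 and 3 did not pass, with the same count adjusted over the list alone. In the fit without the 3 clones at the ends of the span trend, 1 immediate early gene, 1 metallothionein list gene and 1 interferon-stimulated gene were lower, and 0 of these lists' genes were higher. The genes that lost their call differed there by -0.99 (JUNB), -0.45 (DUSP1), -0.50 (MT2A), -0.51 (IFITM3), -1.92 (BST2) and 0.50 (SAMD9L), and the immediate early median was -0.29.

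The list of the constitutive centromere network, to which CENPU belongs, also held loading factors of centromeric chromatin and MLF1, which binds CENPU and is not a subunit. CENPW, a histone-fold protein, was the 1 subunit that rose, by 1.07 on the log2 scale, and MLF1 rose by 0.63, while CENPT, the partner of CENPW in the network, fell by 0.65, CENPM by 0.65 and CENPX by 0.63. The other 14 of 19 measured members did not pass, among them CENPQ, which binds CENPU in the same subcomplex (1.15), and CENPI (1.36). Adjusted over the list alone, 5 were higher and 3 lower (camera adjusted p = 0.813 with an estimated correlation), and leaving out CENPU 1 or CENPU 4 gave the same counts over all genes. In the outer kinetochore and corona list CLASP1, KNTC1 and SKA3 rose, by 1.01, 0.98 and 0.77, ZWINT fell by 0.53, and 7 of 11 measured members did not pass. Adjusted over the list alone, 6 were higher and 1 lower (camera adjusted p = 0.0156 with the preset correlation and adjusted p = 0.658 with an estimated correlation). Among 19 measured mitotic checkpoint and mitotic kinase genes, AURKB fell by 0.72, SGO2 rose by 0.60 and 17 did not pass, with 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). Without control 2, CENPU 7 and CENPU 13, 1 outer kinetochore gene was higher and 0 lower, with a list median of 0.21 against 0.65 in all clones. The same fit left 0 higher and 1 lower in the centromere network (median 0.02) and 0 in the mitotic checkpoint list (median 0.02). Among genes that lost their call, the log2 difference there was 0.95 for CENPW, 0.58 for MLF1 and -0.43 for CENPX. For KNTC1 it was 0.47, for SKA3 0.50, for ZWINT -0.51, for AURKB -0.58 and for SGO2 0.51.

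Among proliferation genes of G2 and M phase, TOP2A, the topoisomerase of mitotic chromosomes, rose by 1.63, the exchange factor ECT2 by 1.35, cyclin gene CCNB2 by 1.22, and the spindle midzone genes PRC1 and KIF4A by 0.81 and 0.76. In all 5 of 20 measured members rose, 0 fell and 15 did not pass, MKI67 (0.68) among them, and the median log2 difference was 0.66. Adjusted over the list alone, 8 were higher and 0 lower (camera adjusted p = 0.000292 with the preset correlation and adjusted p = 0.658 with an estimated correlation). Without control 2, CENPU 7 and CENPU 13, 0 of its members passed in limma and the median was 0.19.

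Of the 6 S phase and DNA replication genes that passed, 5 were lower and 1 was higher. E2F1, the transcription factor of the G1 to S transition, fell by 0.96, CDC45 by 0.68, UHRF1 by 0.53, the flap endonuclease FEN1 by 0.50 and MCM7 by 0.42, while MCM6, another subunit of the replicative helicase, rose by 1.09. The other 16 of 22 measured members did not pass, and the median log2 difference was -0.35. Adjusted over the list alone, 2 were higher and 9 lower (camera adjusted p = 0.0133 with the preset correlation and adjusted p = 0.514 with an estimated correlation). Of 12 measured genes of repair by recombination, RAD54L and XRCC3 fell, by 0.73 and 0.50, and 10 did not pass, with 5 higher and 2 lower adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). The list median was 0.47, and leaving out CENPU 1 gave 4 higher and 2 lower over all genes, while leaving out CENPU 4 gave 5 higher and 2 lower. Among 13 measured p53 target genes CCNG1 rose, PLK3 fell by 0.58 and 11 did not pass, with the same counts, 1 and 1, adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). Of 15 measured apoptosis regulators the BH3-domain gene BID fell by 0.58 and 14 did not pass, with 1 lower adjusted over the list alone (adjusted p = 0.514 with an estimated correlation). None of the 5 measured cyclin-dependent kinase inhibitor and senescence genes passed in limma, CDKN2A (0.08) included, also adjusted over the list alone (adjusted p = 0.891 with an estimated correlation). Without the 3 clones, 0 S phase genes were higher and 4 lower (median -0.26), 0 repair genes higher and 2 lower (median 0.08), 1 p53 target higher and 0 lower, and 2 apoptosis genes lower.

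Of 23 measured cytosolic ribosomal protein genes 7 rose, among them RPS23 by 0.81, RPL27 by 0.71 and RPL19 by 0.65, 0 fell and 16 did not pass, with 10 higher adjusted over the list alone. After quantile normalization 4 rose, and after median centring 3 did, with medians of 0.192 and 0.215. The median on the deposited values was 0.27 (camera adjusted p = 0.00172 with the preset correlation, adjusted p = 0.436 with an estimated correlation). Of 8 measured oxidative phosphorylation genes, UQCRC2, a core subunit of complex III, rose by 1.23, and the cytochrome oxidase subunits COX7B, COX6C and COX5A rose by 0.78, 0.59 and 0.46, whereas 4 did not pass. There were 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.514 with an estimated correlation). ACACA and ACLY, which supply malonyl-CoA and acetyl-CoA for lipid synthesis, rose by 1.44 and 0.50 among 20 measured cholesterol and fatty acid genes, and 18 did not pass, with 2 higher adjusted over the list alone (camera adjusted p = 0.0468 with the preset correlation and adjusted p = 0.813 with an estimated correlation). In the unfolded protein and integrated stress response list ASNS, the asparagine synthetase, and PHGDH rose, by 0.95 and 0.53, and 13 of 15 did not pass, with 3 higher adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). LDHA rose by 0.58 among 16 measured hypoxia and glycolysis genes, of which 15 did not pass and 2 were higher adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). Of 15 measured MYC target and ribosome biogenesis genes NOLC1 and LDHA rose, by 0.81 and 0.58, WDR74 and RRS1 fell, by 0.45 and 0.37, and 11 did not pass, with 3 higher and 2 lower adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). Fewer passed without the 3 clones, with 3 ribosomal protein genes higher (median 0.17), 1 oxidative phosphorylation gene (median 0.27) and 1 cholesterol and fatty acid gene (median 0.00). In that fit 0 genes of the stress response, hypoxia and MYC lists passed in either direction, with ASNS at 0.84, PHGDH at 0.43, LDHA at 0.42, NOLC1 at 0.57, WDR74 at -0.31 and RRS1 at -0.45.

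**Figure D3:**
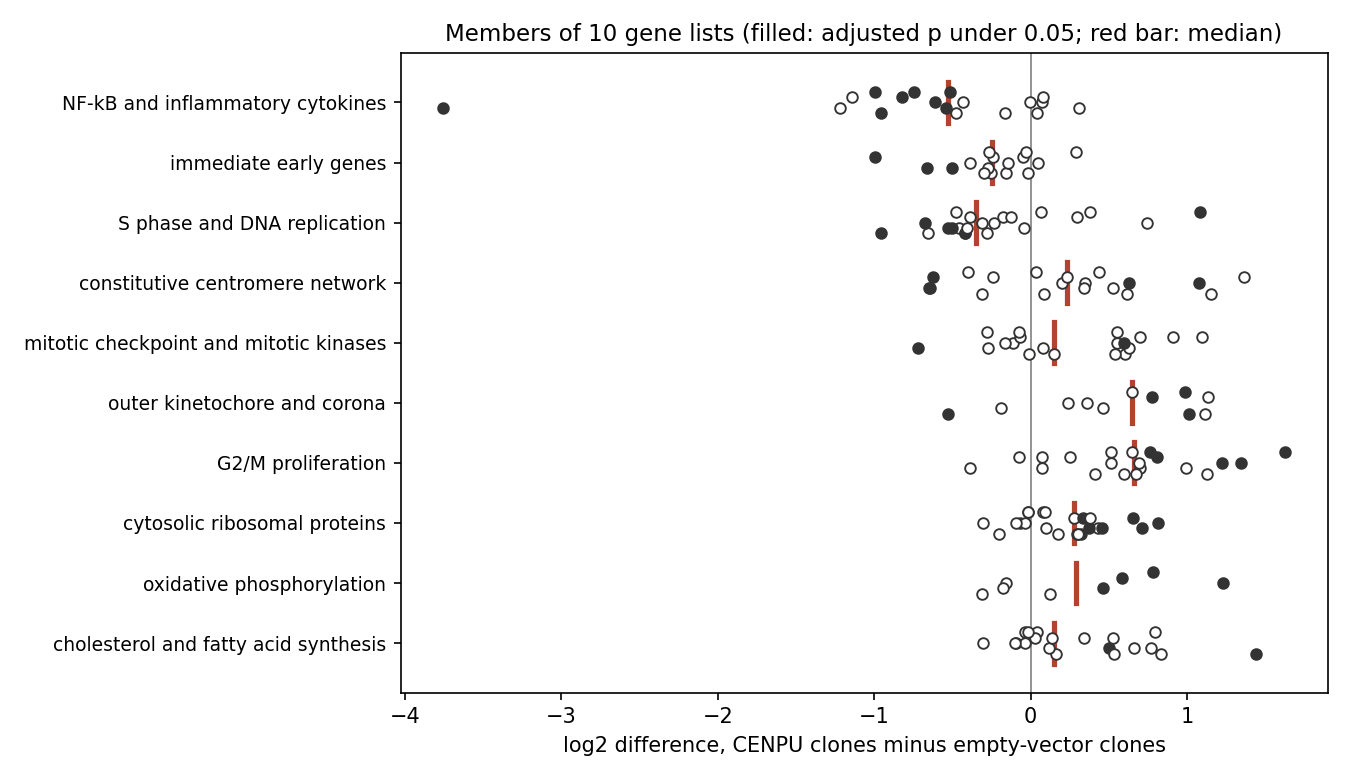
Log2 difference between CENPU and empty-vector clones (horizontal axis) for each measured member of 10 gene lists. Each circle is 1 gene, filled where it passed in limma over all genes, and the red bar is the list median, which ran from -0.53 for the NF-kB and inflammatory list to 0.66 for the G2/M list.

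The mesenchymal intermediate filament gene VIM rose by 0.74 and FN1 rose, while 12 of 14 measured mesenchymal markers did not pass, with 2 higher adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). TJP1, a tight junction scaffold, rose by 0.98 among 21 measured epithelial markers, of which 20 did not pass and 1 was higher adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). EGFR and DST rose, by 0.87 and 0.93, among 9 measured basal prostate markers, and 7 did not pass, with 2 higher adjusted over the list alone (adjusted p = 0.514 with an estimated correlation). HOXB13 and AGR2 rose, by 0.42 and 0.50, among 9 measured luminal markers, and 7 did not pass, with 2 higher adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). HERC3 rose by 0.92 and HOXB13 rose among 12 measured androgen receptor genes, and 10 did not pass, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.514 with an estimated correlation). In the prostate cancer gene list ETV5 rose by 0.54, CLU fell by 0.58 and 16 of 18 did not pass, with 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.989 with an estimated correlation). TIMP1, an inhibitor of matrix metalloproteinases, fell by 0.84, and the other 12 measured matrix and protease genes did not pass, with 1 lower adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). ZNRF3, which removes Wnt receptors from the membrane, fell by 0.40 among 17 Wnt pathway genes, of which 16 did not pass and 1 was lower adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). EGFR was the 1 member that passed among 25 measured receptor tyrosine kinases and ligands, and the 1 that was higher adjusted over the list alone, with 24 not passing (adjusted p = 0.989 with an estimated correlation). Without the 3 clones, 0 luminal, androgen receptor, Wnt and CENPU neighbour genes passed, with HOXB13 at 0.35, AGR2 at 0.40, HERC3 at 0.70, ZNRF3 at -0.43, UFSP2 at 0.76 and TRAPPC11 at 0.72, and 2 basal markers were higher. In that fit 2 mesenchymal markers were higher and 1 lower, 1 epithelial marker was higher and 1 lower, and 1 prostate cancer gene was lower.

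No member passed in limma, over all genes or adjusted over the list alone, in 7 further lists. These were neuroendocrine markers (15 measured, adjusted p = 0.906 with an estimated correlation), integrins and adhesion genes (10 measured, adjusted p = 0.906), YAP and TGF-beta targets (12 measured, adjusted p = 0.813) and cancer-testis antigens (6 measured, adjusted p = 0.658). The markers of other cell types made up the rest, with 5 fibroblast genes (adjusted p = 0.813), 6 immune cell genes (adjusted p = 0.67) and 7 endothelial genes (adjusted p = 0.658), all from camera with an estimated correlation. Without the 3 clones 1 YAP or TGF-beta target was lower, and without CENPU 1 alone 3 were. After median centring 2 of these targets and 1 immune cell gene were lower. DCN and LUM, abundant in fibroblasts, stood at 2.73 and 2.95 in CENPU clones and 2.81 and 2.99 in control clones. None of the 15 replication-dependent histone genes had a named row.

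Of the 36 lists tested, 0 passed in camera with an estimated correlation, and 2 had an unadjusted p under 0.05, NF-kB and inflammatory cytokines (0.0137) and cytosolic ribosomal proteins (0.0242). With the preset correlation 7 passed, and none of the 7 held with the estimated correlation. With fry, which asks whether the members of a list move one way on balance and does not compare them with other genes, 10 passed. Besides the NF-kB, immediate early, S phase and ribosomal protein lists, these were the metallothionein, oxidative phosphorylation, apoptosis, androgen receptor, basal marker and CENPU neighbour lists. In 7 lists (p53 targets, epithelial, mesenchymal, YAP, receptor kinase, MYC and prostate cancer genes) the median, the mean and the direction of the test did not all have the same sign. The count of members that passed moved by over 1.5 times in 27 of the 36 lists when 1 clone was left out. Higher members then numbered 1 to 6 in the outer kinetochore list, 1 to 7 in the G2/M list, 1 to 5 in the cholesterol and fatty acid list and 1 to 3 among p53 targets, with 0 to 2 p53 targets lower. Lower members numbered 4 to 9 in the NF-kB list and 3 to 6 in the S phase list.

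Over all genes the CENPU clones and control clones stood apart. Of the total sum of squares, 35.3% lay between the groups (exact permutation p = 0.00794 over all even splits of the 10 clones, the smallest value these allow). The first principal component held 58.4% of the variance and ranked the clones in the same order as their correlation with gene span, from control 2 to CENPU 13. On it CENPU 1 (-10.6) lay inside the control range of -45.7 to -6.97, and CENPU 4 (-4.58) lay just above that range. The second held 12.2%. There CENPU 1, 4 and 5 lay at 19.8, 19.9 and 20.7. CENPU 7 (-8.06) and CENPU 13 (-9.39) lay inside the control range of -13.3 to -2.55, so neither component alone separated the groups. CENPU clones lay farther from their own group centroid than control clones did, at 39.9 ± 6.16 (SD, n = 5) against 27.0 ± 6.89 (SD, n = 5) in log2 units over all genes. The difference of 12.8 had exact two-sided permutation p = 0.0238, and did not pass without CENPU 1 (11.2, exact permutation p = 0.0556), CENPU 4 (12.5, 0.0635), CENPU 13 (10.1, 0.0556) or control 4 (11.1, 0.0556).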

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

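Of the tests reported in this part, those of the unnamed block, the span test across clones, the span test within the 4 brighter quintiles of genes, the removal of the span trend with the change it made to the NF-kB list, the fit without 3 clones and the comparisons of handling and labelling were chosen only after the result they bear on was seen.

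Among 56 groups of 5 values examined, 4 held a clone far from the other 4, where chance would give about 2.8. RPL21P28 stood at 9.22 in CENPU 4, against 10.1 to 10.3 in the other CENPU clones. MTREX stood at 4.82 in control 2, against 6.09 to 6.50 in the other controls. LRRC14 stood at 6.79 in CENPU 5, against 7.27 to 7.43 in the other CENPU clones. EDN1 stood at 6.93 in control 3, against 5.59 to 5.75 in the other controls. Rows without a gene name were not used in the gene counts, and 333 of them passed in limma and were higher by a log2 difference of at least 1 in CENPU clones, with 101 lower by as much.

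The 1504 genes that differed, CXCL5 and GKN2 among those with the largest falls, were set against 100 randomly drawn splits of the clones into equal groups, the real one included. The real split, 1 of 100, gave as many, and the highest count in any other was 1 gene. A chance division of the clones is thus argued against for this count, at 1 in 100, the smallest share these splits allow. All other splits mixed clones of both groups, so a difference between the groups widens the spread within them and lowers their counts. For the gene lists, 0 passed in the real split, so all 100 splits gave at least that whatever their values, and the comparison decides nothing. The highest other split gave 1.

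The first pattern was the rise of genes of long span, such as DST, AQR and IQGAP1, in CENPU clones. Bootstrap intervals in this part resampled genes or rows and not clones, so they do not measure the spread between clones. The brightness of the rows is argued against for the 4 brighter quintiles of genes, where the correlation of span with the log2 difference was 0.292 to 0.444, and left open for the dimmest quintile, where it was 0.121 with a 95% bootstrap interval of 0.0834 to 0.158. A trend that varies between clones whatever their group cannot be told apart from a difference between the groups, because the group means differed (exact two-sided permutation p = 0.0159) while the clones overlapped, with CENPU 1 at -0.160, inside the control range. A handling or labelling difference between the arrays of the groups, for example in RNA integrity, could also give a trend with span, and no label gives the dates or batches that would separate it from CENPU. A biological effect of CENPU on long genes stays open and untested.

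The second pattern was the unnamed block at the end of the table, where the mean of all 47 bright rows was lower in every CENPU clone (9.98 to 10.5) than in any control clone (11.1 to 11.8). The authors' normalization between arrays is argued against for rows of a brightness of 10.3 to 11.7. There 248 named rows had a median log2 difference of -0.107, with a 95% bootstrap interval of -0.148 to -0.0565. Those bounds are the quartiles of the rows of the block that passed, and not of all 47 bright rows. A labelling difference between the arrays of the groups may account for the block, if its rows are control probes for RNA added during labelling, but their identity is not known here and the groups were separated by a gap of 0.566 on the log2 scale. Such a difference cannot be told apart from the CENPU vector, since every CENPU clone lay on one side. An effect of CENPU on human transcripts among these rows stays open and untested.

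The third pattern was the lower level of 8 of 18 NF-kB and inflammatory genes, CXCL5, CXCL2, ICAM1 and CXCL3 among them, in a list that did not pass (camera adjusted p = 0.436 with an estimated correlation). The clones at the ends of the span trend are argued against only as the whole cause of the low list median. Without them it was -0.487 (95% bootstrap interval over genes -0.76 to -0.127). That interval does not measure the spread between clones. The list did not pass in that fit either (camera adjusted p = 0.234 with an estimated correlation), so a fall beyond the spread of the remaining clones stays open. Removal of the span trend changed the log2 differences of the 18 members by a median of 0.0953 (95% bootstrap interval over genes 0.0826 to 0.0983). It left 7 of the 8 passing, while CSF1 went from -0.61 to -0.59 (limma adjusted p = 0.0533). Across protein-coding genes the median absolute change was 0.0807, so removal could hardly have undone a fall of this size in any list. The values show only that the trend as fitted was too small to be the whole of the fall. The list median after removal was -0.505, but its interval, -0.78 to -0.083, reached just past the bound of -0.1 set for it, so a part played by the trend stays open. A handling difference between the groups could lower these genes and cannot be told apart from an effect of CENPU, since no label gives batches, and both stay open.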

How the results depend on the processing

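Removal of the span trend, and the fit without control 2, CENPU 7 and CENPU 13, were chosen only after the result was seen. The CENPU level kept its direction and side of the threshold under every alternative run, with CENPU differing by 2.81 to 3.24. The lowest of these, with clone number as a block, rests on clones 1, 4 and 5 of each group alone. The separation of the groups, a share that has no direction, kept its side of the threshold under every alternative run for it. The number of genes rested on the clones included and on the threshold. Without those 3 clones it was 470 (209 higher, 261 lower, 80 by a log2 difference of at least 1), and 369 of these were among the 1504. At thresholds of 0.01 and 0.10 it was 253 (130 higher, 123 lower, 86 by at least 1) and 2588 (1408 higher, 1180 lower). With ordinary variances it was 733 (287 higher, 446 lower, 108 by at least 1), and with array weights 1303 were higher. The cause of these changes was not tested. Without the 3 clones FN1 went from 2.21 to 1.28 and the G2/M median from 0.66 to 0.19, whereas leaving out CENPU 1 or CENPU 4 raised the count, to 2471 and 1973. Quantile normalization gave 754 higher and 952 lower, and median centring 731 higher and 911 lower, against 791 and 713.

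Leaving out 1 clone gave 613 to 2471 genes, 297 to 1463 higher, 316 to 1008 lower, and 129 to 537 by at least 1. The total moved by over 1.5 times without CENPU 1 (2471), CENPU 5 (864), CENPU 7 (688), CENPU 13 (801), control 2 (687), control 3 (820), control 4 (613) and control 5 (835). The count by at least 1 moved as far without CENPU 1 (537), CENPU 4 (431), CENPU 7 (149), CENPU 13 (145), control 2 (129) and control 4 (142). The difference in spread was 10.1 to 16.9. For the gene lists, 7 passed with the preset correlation and 10 with fry, against 0 in camera under every other alternative run, where the first assumes a smaller correlation between genes and fry tests another hypothesis, that the members of a list did not change. Of 1911 values of 87 named genes under alternatives, 1549 kept their side of the threshold, 362 no longer passed and 0 changed sign. These genes were taken because they passed, so they could only keep or lose their call. Other thresholds, trend and robust fitting, ordinary variances and the use of all rows could not change a sign, because they leave the log2 difference as it was. Of the 87, 78 did not pass with clone number as a block, which compares clones 1, 4 and 5 of each group alone. Calls were lost by 52 at a threshold of 0.01, 46 without the 3 clones and 26 with ordinary variances. With the span trend removed, which changed the differences little, 4 lost their call. Leaving out 1 clone ended 0 to 24 of these calls.

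Clone numbers 1, 4 and 5 occur in both groups, but same-numbered clones did not deviate together, with correlations of -0.379, 0.104 and 0.0227, and each of the 3 CENPU clones correlated best with a control of another number. These 3 correlations gave no sign that the numbers pair the clones, but they are too few to exclude a shared handling of same-numbered clones. The numbers were treated as names only. With clone number as a block, 55 genes passed (22 higher, 33 lower, 47 by at least 1) and CENPU differed by 2.81. Clones whose number occurs in only 1 group are fitted exactly by this block, so it compares clones 1, 4 and 5 of each group alone. The block leaves few residual degrees of freedom. Signal over background was not available per probe, so how far dim rows understate a difference was not measured.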

Other observations

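Of the tests in this part, the family of aminoacyl-tRNA synthetases and the 2 microRNA rows were taken up only after values of EPRS1, LARS1, GARS1, MIR578 and MIR1471 had been seen.

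Many enzymes that charge tRNAs were higher in CENPU clones. Beside EPRS1, LARS1 rose by 1.62 and GARS1 by 1.57 on the log2 scale. Of 17 measured cytosolic synthetases 11 rose and 0 fell, among them TARS1 by 1.39, RARS1 by 1.04, CARS1 by 0.81 and WARS1 by 0.65. QARS1 (-0.11) and VARS1 (-0.04) did not pass. A shared rise of the whole family is a hypothesis formed from the first 3 members. The other 14 had a median log2 difference of 0.622, 12 were above 0 and 8 passed in limma, but the list test gave camera p = 0.0804 with an estimated correlation against 3.81e-07 with the preset one, so whether the family moved beyond other genes stays open.

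The MIR578 row stood at 8.34 ± 0.29 (SD, n = 5) in CENPU clones and 3.53 ± 0.27 (SD, n = 5) in control clones, 28.0-fold apart. Its control level lay near the lower quartile of the control arrays (3.38 to 3.44), where background signal remains, so the exact fold is uncertain. The MIR1471 row stood at 7.60 ± 0.24 (SD, n = 5) and 4.27 ± 0.38 (SD, n = 5), a log2 difference of 3.33 (limma adjusted p = 4.06e-08 and 4.74e-06). A rise of the whole region around each was tested as an explanation and is argued against. The named genes within 1000000 bases of each had median log2 differences of 0.219 for the 6 around MIR578 and 0.00741 for the 19 around MIR1471. What transcript these rows measured was not tested.

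Clones of both groups carried runs of neighbouring genes shifted together, which copy-number differences between clones could produce. The order of 9243 expressed protein-coding genes in RefSeq (GRCh38.p14) was scanned in windows of 25 genes, after removal of the span trend, against 200 shuffled orders. Of 1748 windows, 51 in CENPU 4 lay beyond the shuffled limit. Windows overlapped and the limit was set in each clone, from 0.176 in control 1 to 0.794 in CENPU 13, so the numbers cannot be compared between clones. The longest run in CENPU 1 went from GTPBP6 to GAGE12H over 17 windows and reached a median of -0.625. In CENPU 5, a run from ATF2 to CNOT9 covered 12 windows and reached 0.707. In control 2, a run from APCDD1 to MRO covered 9 windows and reached -0.781. Named genes can lie in such runs. PREPL began a window with a median of 0.825 in CENPU 13, and COX7B began a window with a median of 0.743 in CENPU 5. USP18, lower in CENPU clones, began a window with a median of 0.289 in control 5. FN1 lies on chromosome 2, as does the run from ATF2 to CNOT9. TSPAN6 lies on chromosome X, where a window from NAP1L2 to TCEAL4 was raised in CENPU 5 (0.777), CENPU 7 (0.642) and CENPU 13 (0.946). Whether FN1 and TSPAN6 lie inside these stretches was not examined. The rises and falls of single genes were not separated from those of their neighbours, and the place of the other named genes was not examined. Some runs in CENPU 7 and CENPU 13 had the same ends, such as PAG1 to MTERF3 (0.677 and 1.01), and the run from GALNT12 to PTBP3 was shared by CENPU 1 and CENPU 4 (-0.293 and -0.253), so a trend along the genome shared by clones may contribute, and DNA copy number was not measured here.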
